A study of Homo sapiens with 4 samples.

How the data were processed

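Single-cell RNA sequencing was done on 4 cultures of LNCaP cells, an androgen-sensitive line of human prostate adenocarcinoma. One culture received DMSO, the solvent, at 0.1%, and 3 received enzalutamide, an antiandrogen, at 5 µM for 4, 7 or 14 days. Per the labels' protocols, the dishes were seeded alike, cells were released with trypsin, and libraries were made on the Chromium droplet system of 10x Genomics. Each group held 1 library, so the spread between cultures could not be measured. Per the labels' protocols, the DMSO culture was harvested by its confluency, so its time in culture was not matched to any enzalutamide culture.

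The deposited matrices held whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, 1 matrix per library, with no normalization. They were written by Cell Ranger 6.0.1, per the file headers. STAR, Seurat and the hg38 build were named in the submitters' processing notes, without a role or order. The annotation release and whether introns were counted were not given in the sources used here. Each matrix listed 36601 genes and barcodes already called as cells, so empty droplets were not analysed here and free RNA could not be estimated from them. Reads that match near-identical genes were not resolved here. Values of the UGT2B family, KLK2 and KLK3, the metallothioneins, the histones and TRGC1 are uncertain to that degree. Strand handling was not given in the sources used here, so HOXA11-AS could not be separated with certainty from its sense partner.

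Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept. This left 9126 of 10680 DMSO barcodes, 10944 of 11427 at 4 days, 11147 of 11620 at 7 days and 6154 of 6890 at 14 days. Most of those left out exceeded the mitochondrial limit, 1494, 471, 420 and 677 barcodes in the same order. UMIs were summed over the kept cells of a library and divided by the library total and scaled to counts per 1e6 UMIs (CPM). Exact 95% Poisson (Garwood) intervals were set on each sum and exact Clopper-Pearson intervals on each share of cells. These intervals cover counting error only. For named genes at 20 CPM or more the interval reached at most 3.16% of the value to either side, and for those at 5 CPM or more at most 6.45%. A count of 0 allowed up to 3 counts, which came to between 0.0125 and 0.0154 CPM in the 4 libraries.

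Comparisons were differences of log2(CPM+1), enzalutamide against DMSO at each time, then 7 days against 4 and 14 days against 7. This scale understates the difference of genes near or under 1 CPM. No statistical test was possible with 1 library per group, so no p-value is given and genes were named by size. The groups, the comparisons, 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 8 largest positive and 8 largest negative differences against DMSO among genes with at least 20 CPM in either library. It took 4 in each direction between successive times, up to 2 highest and 2 lowest measured members of each list at 14 days, and 16 genes chosen from the biology of the line. Genes named outside this rule are said to have been chosen after their values were seen, apart from genes that lead a cluster or hold the most UMIs of a list. XIST and Y-linked genes were left out of the naming, and some genes that the rule took are not reported here.

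List members were measured if they reached 5 CPM in at least 1 library, as 11165 genes did. The median difference of a list was given with its exact order-statistic 95% interval over members and with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Members were counted above or below a difference of 1.5 times. Of the 32 lists, 2 had no measured member. Over the measured genes the median difference from DMSO was -0.02 at 4 days, -0.01 at 7 days and 0.23 at 14 days, and it was 0.24 at 14 against 7 days. List medians and member counts at 14 days are therefore given relative to that shift unless they are called unshifted or by the library total.

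For shares of cells, phases and list shares per cell, each cell was thinned without replacement to 7000 UMIs. This left out 129 DMSO cells, 189 at 4 days, 503 at 7 days and 130 at 14 days as too shallow. Phases came from the cell cycle scoring of scanpy 1.11.5 with a score threshold of 0 on the 4 libraries together. Clusters came from 2000 highly variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at a resolution of 0.5, with no integration of libraries. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Gene positions came from GENCODE release 29 on GRCh38, in which 34616 of the gene identifiers had a record.

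The pseudobulk steps were tested on simulated data with 200 genes changed by known folds among 11165. Both simulated libraries were Poisson counts drawn from the DMSO profile, so spread between cells or cultures was not simulated. The simulation therefore checks the calculation and counting error only. In the simulated comparisons at 4, 7 and 14 days, 94.9%, 95.5% and 94.85% of intervals held the true value, and the sign was right for 100% of the genes at each of the folds 1.5, 2 and 4. The list of changed genes reached percentile 100, and 6, 6 and 4 of 100 lists of unchanged genes fell outside the central 95%. The doublet caller Scrublet marked 0 DMSO cells, 833 cells at 4 days, 1 cell at 7 days and 0 cells at 14 days. It had not worked in 3 of 4 libraries, so no doublets were removed, and leaving out the 8% of cells with the most UMIs in each library took its place. The other alternatives were all barcodes, stricter cell limits, median-of-ratios size factors, equal weight per cell, thinned sums, a pseudocount of 0.1 CPM, other limits on list members, and other thresholds for phases, shares and clusters. After the data were seen, alternatives were added that left out cells scored in S or G2/M, cells high in interferon response genes, and a cluster low in MALAT1.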

Results

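The data were UMI counts from 4 droplet libraries of LNCaP cells, 1 per group, with cells grown in DMSO or in 5 µM enzalutamide for 4, 7 or 14 days. The kept cells held 240058737 UMIs in DMSO, 221024098 at 4 days, 195072489 at 7 days and 220579000 at 14 days. The median cell held 24413, 17990, 14293 and 30211 UMIs and 5175, 4279, 3807 and 6206 genes in the same order, with 4.26%, 6.43%, 3.74% and 4.94% mitochondrial UMIs. Ribosomal protein genes took 25.6%, 28.2% and 26.8% of UMIs in DMSO and at 4 and 7 days, and 17.8% at 14 days. The study asked how the transcriptome of these cells moves over a course of antiandrogen treatment and whether neuroendocrine features appear. With 1 library per group there was no replicate check on any difference. All 3 comparisons with DMSO used the same DMSO library, so part of the likeness between times may come from it.

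The comparison of 4 days of enzalutamide with DMSO asked what early antiandrogen treatment does. Transcripts of androgen-induced genes were far lower in the enzalutamide cells. KLK3, which encodes prostate-specific antigen, had 1059 CPM (1055 to 1064) in DMSO and 22.8 CPM (22.2 to 23.5) at 4 days. Its neighbour KLK2, a related kallikrein, had 167 CPM (165 to 168) and 2.44 CPM (2.24 to 2.65). The serine protease gene TMPRSS2 stood at 121 and 18.3 CPM, and FKBP5, a co-chaperone of steroid receptors, at 178 and 23.2 CPM. Of 34 measured androgen-induced genes, 30 were below DMSO by over 1.5 times and 0 above, with a median difference of -2.02 (-2.88 to -1.32) and percentile 0 among random lists.

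The largest negative differences at 4 days included several genes outside that list. HPGD, the enzyme that inactivates prostaglandins, had 108 CPM (107 to 109) in DMSO and 0.638 CPM (0.537 to 0.752) at 4 days. The noncoding AP000527.1 had 142 and 1.01 CPM, the noncoding AL589182.1 110.2 and 3.203 CPM, and TRGC1, a T-cell receptor constant segment whose locus is transcribed in prostate epithelium, 110.3 and 2.06 CPM. AFF3, a nuclear factor linked to transcription elongation, had 57.4 and 0.918 CPM, and the sialyltransferase gene ST6GALNAC1 46.6 and 0.457 CPM.

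Genes known to be held down by androgen were higher at 4 days. In the androgen-repressed list, 7 of 10 measured genes were above DMSO by over 1.5 times and 0 below, with a median of 1.87 (0.13 to 3.66) and percentile 100. OPRK1, the kappa opioid receptor, had 0.479 CPM (0.396 to 0.575) in DMSO and 37.2 CPM (36.4 to 38.0) at 4 days. UGT2B17 and UGT2B15, which conjugate androgens with glucuronic acid, had 10.997 and 6.22 CPM in DMSO and 98.7 and 90.2 CPM at 4 days. CAMK2N1, an inhibitor of calmodulin-dependent kinase II, had 132 and 985 CPM. Among genes with at least 20 CPM in either library, the largest positive difference was in PLA2G2A, a secreted phospholipase, with 3.72 CPM (3.48 to 3.97) and 183 CPM (182 to 185). FBXO2, an F-box protein, had 3.199 and 39.3 CPM, the kinase gene MAST4 26.1 and 184 CPM, and the zinc finger gene MYNN 19.3 and 133 CPM.

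At 4 days G2/M genes were on balance close to DMSO and S-phase genes a little lower. The G2/M list had a median of -0.01 (-0.19 to 0.11), with 3 of 54 genes above and 8 below by over 1.5 times. The S-phase list had a median of -0.29 (-0.39 to -0.09), with 10 of 43 genes below and 0 above, at percentile 0.16 among random lists. CDK1, the mitotic kinase, named after its values were seen, had 340.4 CPM in DMSO and 156 CPM at 4 days. MKI67, the proliferation antigen, had 95.9 and 83.8 CPM, and the topoisomerase TOP2A 141 and 107 CPM. The luminal identity list differed by -0.13 (-1.05 to 0.10), with 5 of 16 genes below by over 1.5 times and 0 above. Its regulators FOXA1 and HOXB13 had 207 and 115.97 CPM in DMSO and 217 and 125 CPM at 4 days.

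The comparison of 7 days with DMSO asked whether the early state holds. KLK3 and KLK2 were lower still, at 13.9 CPM (13.4 to 14.5) and 1.34 CPM (1.19 to 1.52), and FKBP5 stood at 13.2 CPM. TMPRSS2, at 19.3 CPM, was close to its 4-day level. Of the 34 androgen-induced genes, 31 were below DMSO by over 1.5 times, and 1 was above, the metalloreductase gene STEAP2, with 382 CPM in DMSO and 630.4 CPM at 7 days. The list median was -2.20 (-3.13 to -1.47), at percentile 0. HPGD, AFF3 and ST6GALNAC1 remained under 1 CPM, at 0.687, 0.477 and 0.641 CPM. ADAM7, a metalloprotease-like gene of the reproductive tract, had 26.2 CPM in DMSO and 0.0205 CPM at 7 days, a sum of 4 UMIs.

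Androgen-repressed genes stood further from DMSO at 7 days, with 8 of 10 above by over 1.5 times and a median of 2.86 (0.542 to 4.504). PLA2G2A reached 328 CPM (326 to 331), OPRK1 64.5 CPM, UGT2B17 207 CPM, UGT2B15 163 CPM and CAMK2N1 1583 CPM. The interferon-related IFI27L2 had 0.308 CPM in DMSO and 38.0 CPM at 7 days, and PLAAT4, an acyltransferase induced by retinoids, had 1.90 and 51.2 CPM. The retinol-binding RBP5 had 0.442 and 28.6 CPM, and the noncoding LINC01326 0.158 and 26.3 CPM.

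Proliferation genes were lower at 7 days. The S-phase list had a median of -1.09 (-1.31 to -0.84), with 37 of 43 genes below DMSO by over 1.5 times, and the G2/M list a median of -0.72 (-0.84 to -0.48), with 32 of 54 below; none was above in either list. RRM2, a subunit of ribonucleotide reductase, had 61.6 CPM in DMSO and 19.97 CPM at 7 days, MKI67 39.5 CPM and EZH2, the Polycomb methyltransferase, 55.4 and 26.2 CPM. UBE2C and PTTG1, which act at mitotic exit and in sister chromatid cohesion, were not lower, at 89.3 and 190.2 CPM against 69.8 and 174 CPM in DMSO. Without cells scored in S or G2/M, a setting added after the data were seen, the S-phase median was -0.22 and the G2/M median -0.09. The same genes scored those cells, so this does not separate fewer cycling cells from lower levels per cell.

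The comparison of 14 days with DMSO asked what prolonged treatment does. This library combined lower levels of most proliferation genes, several of them near 0, with a partial return of some androgen-induced genes. MKI67 had 3.55 CPM (3.31 to 3.81) against 95.9 CPM (94.7 to 97.2) in DMSO, TOP2A 4.87 CPM against 141 CPM, RRM2 1.41 CPM, PBK, a mitotic kinase, 4.17 CPM against 224 CPM, and NUSAP1, a spindle protein, 7.34 CPM against 277 CPM. Relative to the shift of all genes, the G2/M median was -3.34, with 50 of 54 genes below by over 1.5 times, and the S-phase median -2.42, with 42 of 43 below. With a pseudocount of 0.1 CPM the unshifted G2/M median of -3.11 (-3.45 to -2.44) became -3.64, and without the cells scored in S or G2/M, mostly DMSO cells, the unshifted medians were -0.78 for G2/M and -0.44 for S. EZH2 had 7.43 CPM, and the oncogene MYC 9.18 CPM against 57.7 CPM in DMSO.

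Growth arrest genes were higher at 14 days, with 10 of 18 above by over 1.5 times relative to the shift and 0 below, and a relative median of 0.62. BTG2, an antiproliferative cofactor, had 107 CPM against 21.4 CPM in DMSO, and TXNIP, an inhibitor of thioredoxin and of glucose uptake, 411 CPM against 93.6 CPM. The p53 target list had a relative median of -0.10, with 2 of 18 genes above and 4 below; by the library total it was 0.14 with 4 above and 2 below, so its direction followed the scale. PHLDA3, a p53 target, had 72.9 CPM against 35.9 CPM, and the death receptor TNFRSF10B 16.4 CPM against 32.3 CPM.

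KLK3 stood at 119.7 CPM (118 to 121) at 14 days, KLK2 at 11.6 CPM and TMPRSS2 at 43.7 CPM, each between its 7-day and DMSO level. A small part of the cells carried most of the KLK3: 335 of 6024 thinned 14-day cells held 83.2% of its UMIs. The other thinned cells had 4.47 CPM of KLK2. FKBP5, at 11.6 CPM (11.1 to 12.0), was below its 7-day level, and HPGD, at 1.28 CPM, stayed far below its DMSO level. Relative to the shift, 27 of 34 androgen-induced genes were below DMSO by over 1.5 times and 2 above, with a relative median of -1.43. The genes above were STEAP2, at 879 CPM, and ACPP, the prostatic acid phosphatase, at 164 CPM against 40.4 CPM in DMSO. Of the androgen-repressed genes, 9 of 10 were above and 1 below, with a relative median of 3.57. PLA2G2A had 2072 CPM (2066 to 2078), CAMK2N1 3018 CPM, UGT2B17 448 CPM, OPRK1 133 CPM and IGFBP3, a binding protein of insulin-like growth factors, 121 CPM against 3.79 CPM in DMSO. The gene below was UGT2B11, at 2.40 CPM against 6.63 CPM. EGLN3, an oxygen-sensing prolyl hydroxylase, had 260.0 CPM against 5.96 CPM in DMSO, and the noncoding HOXA11-AS 43.4 CPM against 0.737 CPM. TMEFF2, a transmembrane protein of prostate epithelium, had 0.712 CPM against 53.2 CPM.

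Luminal identity genes went both ways at 14 days, with 7 of 16 above by over 1.5 times relative to the shift and 3 below, or 9 and 3 by the library total. The relative median was 0.45, and the unshifted median of 0.68 had an interval that held 0 (-0.28 to 1.09). KRT18, a keratin of luminal cells, had 726 CPM against 269 CPM in DMSO, HOXB13 213 CPM against 115.97 CPM and FOXA1 233 CPM against 207 CPM. Those below included ESRP2, a splicing factor of epithelia, at 9.98 CPM against 21.6 CPM, and SPDEF, named after its values were seen, at 40.0 CPM against 71.3 CPM.

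**Figure D1:**
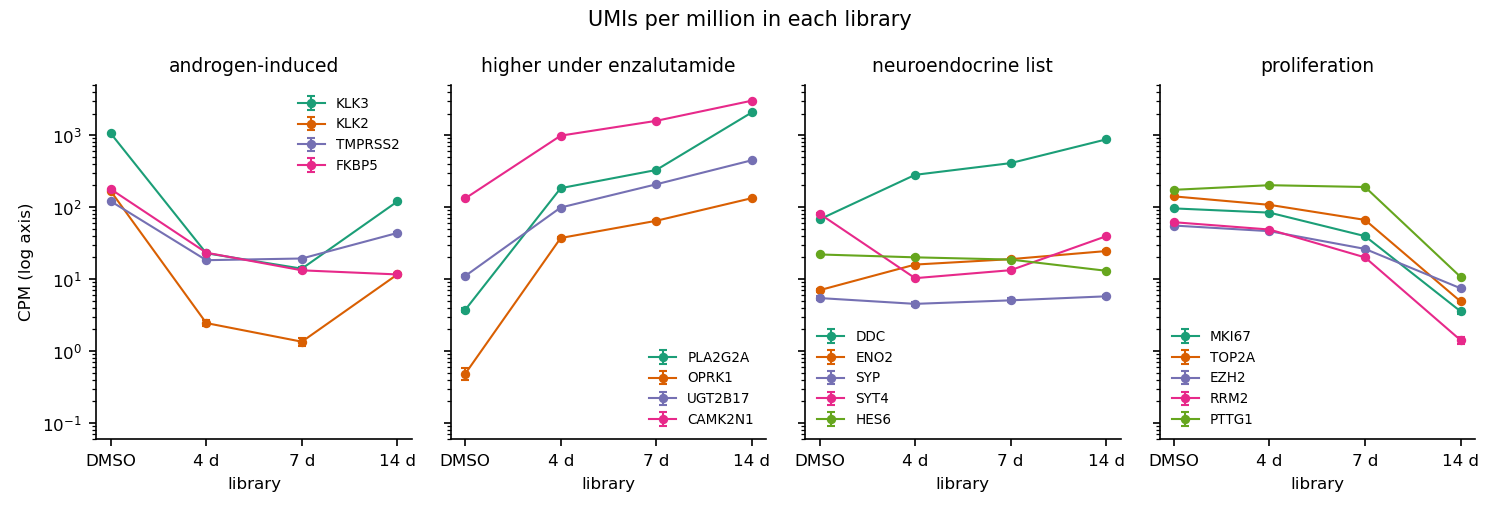
Level of 18 genes in each of the 4 libraries, in CPM on a log axis, with exact 95% Poisson intervals as bars, mostly smaller than the points. KLK3 had 1059 CPM in DMSO and 13.9 CPM at 7 days and stood at 119.7 CPM at 14 days, while MKI67 stood at 95.9, 83.8, 39.5 and 3.55 CPM.

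The enzalutamide libraries were also compared with each other, without DMSO, to ask when along the course each value moved. From 4 to 7 days the androgen-induced median differed by only -0.04 (-0.23 to 0.12), with 1 gene above and 3 below by over 1.5 times, while the S-phase median was -0.81 (-0.94 to -0.66) and the G2/M median -0.62 (-0.68 to -0.56). The linker histone HIST1H1B had 49.3 CPM at 4 days and 14.5 CPM at 7 days, MCM10, a replication initiation factor, 32.2 and 12.0 CPM, and the noncoding HELLPAR 21.6 and 7.47 CPM. The noncoding MIRLET7BHG had 39.1 and 14.4 CPM. Among genes with at least 20 CPM in either library, PLAAT4 and IFI27L2 had the largest positive differences, 1.55 and 1.53, followed by the growth factor midkine (MDK), at 37.9 and 98.2 CPM, and ID1, an inhibitor of differentiation factors, at 209.7 and 494 CPM.

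From 7 to 14 days the picture differed. Relative to the shift of all genes, 18 of 34 androgen-induced genes were higher by over 1.5 times and 2 lower, with a relative median of 0.71 and percentile 100. KLK3 differed by 3.02 and KLK2 by 2.42. The G2/M list was lower, with 49 of 54 genes below and a relative median of -2.66, and the S-phase list with 34 of 43 below and -1.10, or 28 below by the library total. UBE2C had 89.3 CPM at 7 days and 3.21 CPM at 14 days, PTTG1 190.2 and 10.7 CPM, the replication factor PCLAF 139 and 7.87 CPM, and the spindle protein DLGAP5 49.1 and 2.21 CPM. With the same limit of 20 CPM, the largest positive differences were in the noncoding AL627171.2, at 9.89 and 126 CPM, AGR2, a protein disulfide isomerase of secretory epithelia, at 10.8 and 119 CPM, IGFBP3, at 12.7 and 121 CPM, and SPRY4, an inhibitor of receptor tyrosine kinase signalling, at 7.18 and 69.5 CPM. Several genes high at 7 days were low at 14: MYNN had 161 and 25.2 CPM, LINC01326 26.3 and 3.04 CPM, and RBP5 28.6 and 5.34 CPM.

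Whether neuroendocrine genes appeared was asked with a list of 40, of which 9 were measured. The median differed from DMSO by 0.23 (-0.22 to 1.08) at 4 days and 0.45 (-0.29 to 1.32) at 7 days, at percentiles 92.98 and 98.04 among random lists. At 14 days it was -0.05 relative to the shift and 0.18 by the library total, at percentile 46.5, so its sign followed the scale. Members went both ways. DDC, which makes dopamine and serotonin, had 67.5 CPM (66.5 to 68.5) in DMSO and 281, 409 and 874 CPM (870.2 to 878) at 4, 7 and 14 days. ENO2, the neuron-specific enolase, had 6.99, 15.9, 18.9 and 24.5 CPM, and TUBB3, a neuronal tubulin, and CPE, a prohormone peptidase, had 33.0 and 60.8 CPM at 14 days against 16.0 and 23.9 CPM in DMSO. SYP, the synaptic vesicle protein synaptophysin, stayed between 4.51 and 5.74 CPM. SYT4, a synaptotagmin, was lower, with 80.7 CPM in DMSO and 10.3, 13.3 and 39.4 CPM under enzalutamide, and HES6 had 21.9 CPM in DMSO and 13.0 CPM at 14 days. DLL3, a Notch ligand, and ONECUT2 differed from DMSO by 0.17 and 0.18 at 14 days. TUBB3, CPE, DLL3 and ONECUT2, and NEUROD1 and INSM1 below, lay outside the naming rule and are taken as chosen after their values were seen.

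Several other genes of the neuroendocrine list had few or no UMIs. CHGA, encoding chromogranin A, had 0 UMIs in DMSO, which allows up to 0.0125 CPM, and 0.0136 CPM (0.00280 to 0.0397) at 14 days. CHGB reached 0.222 CPM (0.164 to 0.294) at 14 days against 0.0333 CPM (0.0144 to 0.0657) in DMSO, and NCAM1 0.0771 and 0.0375 CPM. Of thinned cells at 14 days, 1 of 6024 held a CHGA UMI, 10 a CHGB UMI, 3 a NEUROD1 UMI and 0 an INSM1 UMI, the last allowing a share of cells with a UMI of up to 0.0498% from 3 counts; such shares do not limit how many cells express a gene. Of unthinned 14-day cells, 45 of 6154 held a CHGB UMI. A gene list of neurites and synapses had a median of -0.39 (-1.08 to 0.81) at 4 days and -0.35 (-1.59 to 0.56) at 7 days, and a relative median of 0.55 at 14 days, with 6 of 12 genes above and 4 below; the unshifted 14-day interval was -1.98 to 1.15. NLGN1, a synaptic adhesion gene, had 41.6 CPM at 14 days against 4.08 CPM in DMSO and MAPT, encoding tau, 20.9 against 6.07 CPM, while the microtubule protein MAP2 had 5.24 against 35.4 CPM and the adhesion gene CNTNAP2 1.46 against 9.46 CPM. The stem and plasticity list had a relative median of -0.94 at 14 days, with 6 of 9 genes below, and its unshifted median of -0.70 had an interval that held 0 (-2.53 to 1.30). SOX9, one of its 2 members above, had 6.497 CPM against 2.05 CPM.

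**Figure D2:**
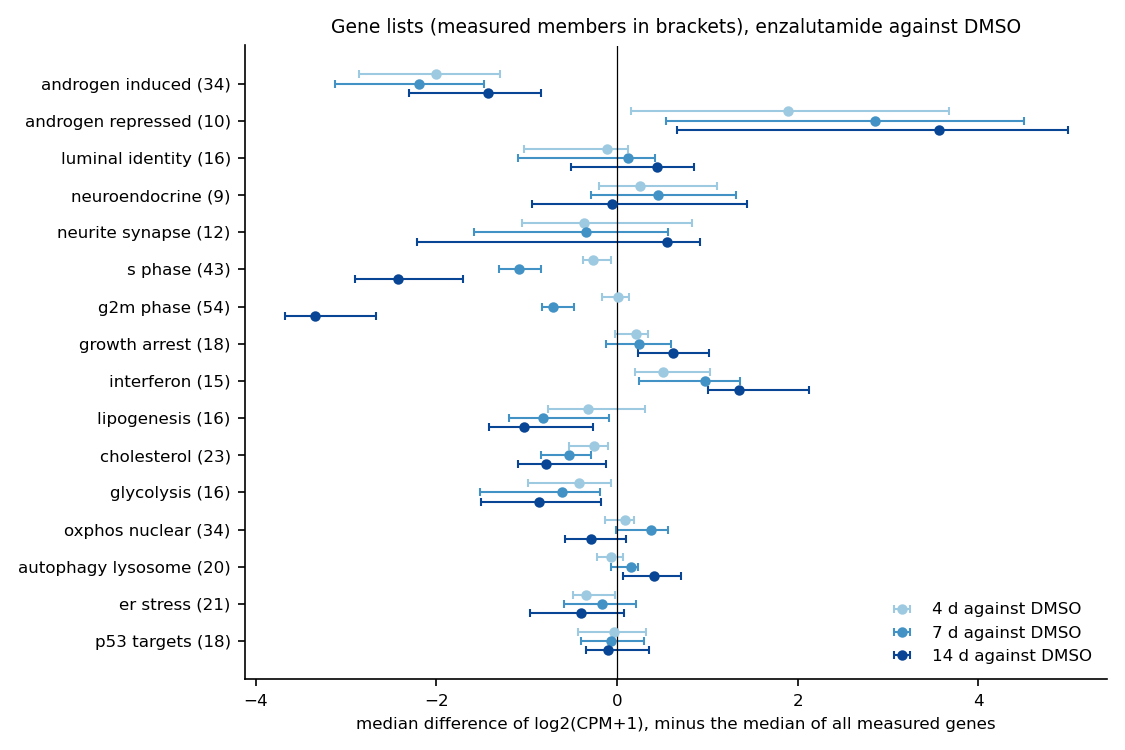
Median difference of log2(CPM+1) from DMSO for 16 gene lists at 4, 7 and 14 days, less the median of all measured genes, with the 95% order-statistic interval over members as bars. Androgen-induced medians lay at -2.00, -2.20 and -1.43 and G2/M medians at 0.01, -0.71 and -3.34; the sign of the neuroendocrine and p53 medians at 14 days followed the scale.

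The share of cells with a UMI was compared after thinning to 7000 UMIs, to ask whether levels were carried by many cells or few. KLK3 was found in 91.9% of DMSO cells (91.4 to 92.5), 6.77% at 4 days, 3.51% at 7 days and 13.6% at 14 days (12.8 to 14.5); unthinned shares were 96.2%, 11.7%, 5.37% and 21.6%. At 14 days the 10% of cells with most KLK3 UMIs held 95.9% of them. DDC was found in 27.1% of DMSO cells and 94.4% of 14-day cells and PLA2G2A in 2.18% and 87.3%; unthinned shares were 51.0% and 98.2%, and 5.83% and 95.7%. No cell type that should lack these genes was present, so the part of each share that free RNA gives was not known. Cells with at least 5 KLK3 UMIs made up 1.14% at 4 days and 0.799% at 7 days and held 54.1% and 58.9% of KLK3 UMIs; Poisson counts of the same mean would put 0.000193% and 1.10e-05% of cells there, so evenly spread free RNA does not account for them. Cells with fewer KLK3 UMIs stay open to that source.

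Phases asked how many cells were in cycle. S or G2/M was called in 45.9% of DMSO cells (44.8 to 46.9), 41.9% at 4 days (41.0 to 42.8), 22.1% at 7 days (21.4 to 22.9) and 0.697% at 14 days (0.503 to 0.941), which was 42 of 6024 cells. The S share was 17.4% in DMSO and 12.5%, 4.91% and 0.133% at 4, 7 and 14 days, and the G2/M share 28.5%, 29.4%, 17.2% and 0.564%. MKI67 was found in 28.1%, 23.5%, 12.2% and 0.880% of thinned cells and in 44.3%, 35.4%, 18.9% and 2.06% of unthinned cells. Cells within 0.05 of the score threshold made up 7.97%, 9.46%, 6.67% and 0.266%. The calls are scored across the 4 libraries together and can be moved by free RNA, so they are read beside the levels of MKI67 and TOP2A.

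**Figure D3:**
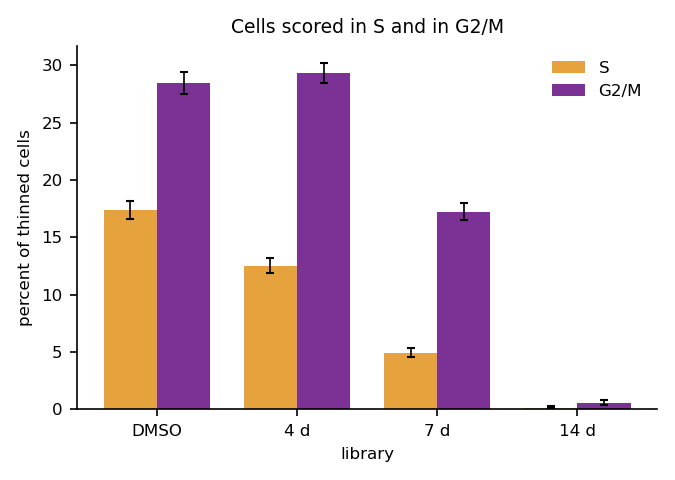
Percent of thinned cells scored in S and in G2/M in each library, with exact 95% binomial intervals as bars. The G2/M share was 28.5% in DMSO, 29.4% at 4 days, 17.2% at 7 days and 0.564% at 14 days.

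The spread of list transcripts over cells asked whether the cells of a library moved together. Androgen-induced transcripts took 0.657% of UMIs in the median DMSO cell and 0.200%, 0.214% and 0.357% at 4, 7 and 14 days. The DMSO 5th percentile, 0.329%, was exceeded by 94.2% of DMSO cells (93.7 to 94.7) and 7.26% of 4-day cells (6.78 to 7.77). At 7 and 14 days 10.2% (9.68 to 10.8) and 57.8% (56.5 to 59.0) of cells exceeded it. Part of these shares came from STEAP2 and ACPP, list members above DMSO at 14 days, STEAP2 also at 7 days. Shares without these genes were not computed. Neuroendocrine list transcripts exceeded the DMSO 95th percentile in 3.71% of DMSO cells, in 968 of 10755 cells at 4 days, and in 16.4% and 53.02% of cells at 7 and 14 days. The higher shares rested on DDC: without it the shares were 3.76% in DMSO and 0.902%, 0.958% and 2.69%, none of them above DMSO. The shares without DDC still hold SYT4, which was lower under enzalutamide. They therefore do not show that no other member rose.

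**Figure D4:**
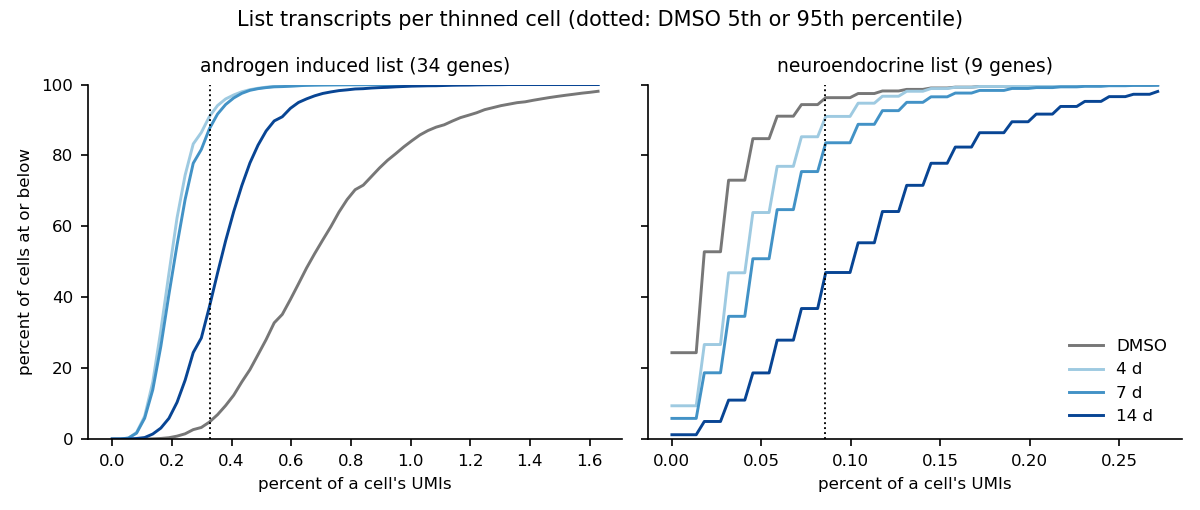
Cumulative percent of thinned cells against the percent of a cell's UMIs from the 34 androgen-induced genes (left) and the 9 neuroendocrine genes (right), 1 line per library; the dotted line marks the DMSO 5th (left) or 95th (right) percentile. Among 14-day cells, 57.8% lay above the androgen-induced line and 53.02% above the neuroendocrine line, the latter 2.69% without DDC.

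Clustering of all 37371 kept cells gave 10 clusters, and 44.9% of cells lay in clusters with at least 80% of their cells from 1 library, which may mark the library and not a type. DMSO cells formed a pair of clusters of their own, one led by MAF, HPGD, KLK3 and KLK2, androgen-active luminal-like, and one led by cell cycle genes such as CDK1, HJURP and NUSAP1. The 4- and 7-day cells shared a large cluster led by LINC01326, MYNN and RBP5, a cycling G2/M-like cluster led by UBE2C, CENPA and CDC20, and a cycling S-like cluster led by DTL, UHRF1 and CDC6. Of 14-day cells, 95.8% lay in 1 cluster, whose leading genes included IGFBP3, EGLN3 and PLA2G2A. Whether the cultures also differed in clone or stock was not tested. No cluster was named neuroendocrine-like, basal-like, fibroblast-like or immune-like. Cluster sizes were not compared between groups, since the genes that define them differ between the libraries.

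Genes of lipogenesis, cholesterol synthesis and glycolysis were on balance lower under enzalutamide. The lipogenesis list had medians of -0.35 (-0.79 to 0.29) at 4 days and -0.83 (-1.20 to -0.10) at 7 days and a relative median of -1.03 at 14 days, with 11 of 16 genes below and 1 above relative to the shift, or 10 and 3 by the library total. ELOVL7, a fatty acid elongase, had 92.3 CPM in DMSO and 2.95, 3.10 and 5.96 CPM, and ACSL3, which activates long-chain fatty acids, 324 CPM and 59.99, 59.2 and 93.8 CPM. The gene above was AGPAT2, of phospholipid synthesis, with 11.5 CPM in DMSO and 46.4 CPM at 14 days. The cholesterol list had medians of -0.28 and -0.53 at 4 and 7 days and a relative median of -0.79 at 14 days, with 14 of 23 genes below and 1 above relative to the shift, or 10 and 2 by the library total; its unshifted interval held 0 (-0.86 to 0.11). HMGCS1, an early enzyme of the pathway, had 51.5 CPM in DMSO and 24.1 CPM at 14 days. The glycolysis list had medians of -0.44 and -0.61 and a relative median of -0.86, with 11 of 16 genes below and 0 above at 14 days relative to the shift, or 8 and 0 by the library total; its unshifted interval held 0 (-1.27 to 0.06). The enolase ENO1 had 715 CPM in DMSO and 356, 242 and 211 CPM, and the hexokinase HK2 7.67, 2.87, 1.70 and 1.18 CPM.

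Interferon response genes were on balance higher at all 3 times, and genes of autophagy and lysosomes on balance higher at 14 days. The interferon list had medians of 0.49 (0.18 to 1.01) at 4 days and 0.97 (0.24 to 1.35) at 7 days and a relative median of 1.35 at 14 days, with 12 of 15 genes above and 1 below. The transcription factor IRF1 had 2.04 CPM in DMSO and 6.68, 8.72 and 20.2 CPM, and IFIT2, an antiviral protein, 1.03, 2.66, 4.18 and 11.2 CPM. The gene below was OAS3, an oligoadenylate synthetase, at 1.65 CPM against 4.34 CPM in DMSO; without cells scored in S or G2/M its difference turned to 0.06. The autophagy and lysosome list had medians of -0.09 and 0.15 at 4 and 7 days and a relative median of 0.41 at 14 days, with 7 of 20 genes above and 1 below relative to the shift, or 11 and 0 by the library total. The lysosomal membrane gene LAMP2 had 85.4 CPM in DMSO and 217 CPM at 14 days.

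The key genes of these comparisons lie as follows on GRCh38 in GENCODE release 29. KLK3 (ENSG00000142515) and KLK2 (ENSG00000167751) are adjacent protein-coding genes on the plus strand of chromosome 19, at 50854915 to 50860764 and 50861568 to 50880567. DDC (ENSG00000132437) lies on the minus strand of chromosome 7 at 50458436 to 50565457. PLA2G2A (ENSG00000188257) lies on the minus strand of chromosome 1 at 19975431 to 19980416 and MKI67 (ENSG00000148773) on the minus strand of chromosome 10 at 128096659 to 128126385. Counts were per gene, so no exon or transcript was resolved.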

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

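The contrasts of 4-day and 14-day values below were chosen after the values had been seen, and none of the differences was tested, since each time had 1 library. Each gene or list median was singled out because the 4-day and 14-day libraries differed from DMSO in opposite directions by over 1.5 times. UGT2B11, a glucuronosyltransferase of the androgen-repressed list, differed from DMSO by 1.19 at 4 days and by -1.16 at 14 days, so the later difference lay -2.36 from the earlier one; its levels were 6.63 CPM in DMSO and 16.4, 21.2 and 2.40 CPM at 4, 7 and 14 days. Its family members UGT2B15 and UGT2B17 were above DMSO at all 3 times, at 95.8 and 448 CPM at 14 days, and reads shared within the family were not resolved. SPRY4 differed from DMSO by -2.13 at 4 days and by 2.31 at 14 days, 4.44 apart, with 13.2 CPM in DMSO and 2.24, 7.18 and 69.5 CPM under enzalutamide. The club cell list, with only 2 measured members, had unshifted medians of -1.78 at 4 days and 1.71 at 14 days, 3.49 apart. Neither member did so alone, and the median joins unlike genes. AGR2 differed from DMSO by -3.92 at 4 days and 0.46 at 14 days, with 85.9 CPM in DMSO and 4.74, 10.8 and 119 CPM under enzalutamide. CP, the copper carrier ceruloplasmin, differed by 0.35 and 2.96, with 0.221 CPM in DMSO and 0.557, 1.17 and 8.49 CPM under enzalutamide.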

How the results depend on the processing

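The settings that left out the 8% of cells with most UMIs, cells scored in S or G2/M, interferon-high cells or the cluster low in MALAT1 were chosen after the data were seen. Of 150 list medians, all unshifted here, 49 lay over 1.5 times from 0, and all 49 kept their direction under every setting except a minimum of 20 CPM per member, where 41 of the 43 with a value did. Fewest stayed over 1.5 times when every member found in the files was used, 25 of 49, since members near 0 CPM then enter. Of 745 differences of named genes, 428 were over 1.5 times, and all 428 kept their direction under every setting except without cells scored in S or G2/M, where 422 did. That setting removes cycling cells by construction, most of them from DMSO, 4 and 7 days. Without them the S-phase medians against DMSO were 0.0470, -0.22 and -0.44 at 4, 7 and 14 days and the G2/M medians -0.0877 and -0.78 at 7 and 14 days. Single genes reversed there: DTL at 7 days to 0.0151, MCM10 at 4 days to 0.16, DDB2 at 14 days to 0.0725, OAS3 at 14 days to 0.0579, and TOP2A at 7 days to 1.03 against DMSO and 0.0723 against 4 days. With a pseudocount of 0.1 CPM the G2/M median at 14 days was -3.64. With members of at least 20 CPM only, the mesenchymal median reversed to -1.18 at 7 days and -0.11 at 14 days, since it then rested on TWIST1 and FN1. Median-of-ratios size factors turned the 14-day medians of the neuroendocrine, p53, hypoxia and Wnt and Notch lists to -0.07, -0.12, -0.07 and -0.05. At a score threshold of 0.1, S or G2/M was called in 38.7%, 33.7% and 17.3% of cells in DMSO and at 4 and 7 days. Without the 8% of cells with most UMIs it was 43.1%, 38.6%, 20.1% and 0.470%, and with stricter cells 43.5% at 4 days. Cells above the DMSO androgen-induced level made up 5.38% at 4 days and 7.96% at 7 days without thinning, and 10.2%, 12.9% and 60.3% at 4, 7 and 14 days without DBI, the member with most UMIs. Cells above the DMSO neuroendocrine level made up 12.1%, 23.9% and 69.6% without thinning and 0.902%, 0.958% and 2.69% without DDC. Clusters numbered 5 at a resolution of 0.25 and 18 at a resolution of 1. Shares of cells with a UMI moved in 94 of 124 cases without thinning and in 102 with thinning to 3500 UMIs, which change the depth, and in 111 when 2 UMIs were asked for at the same depth. The Scrublet alternative was not run. Apart from the causes given by construction, the cause was not tested.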

Other observations

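Further gene groups differed over the course. Metallothioneins, which bind zinc and copper, were near or above DMSO at 4 and 7 days, with medians of 0.29 and 0.60 over 5 genes, and lower at 14 days, with a relative median of -1.87 and 3 genes below and 2 above. MT2A had 740.1 CPM in DMSO, 907 and 900.2 CPM at 4 and 7 days and 198 CPM at 14 days, and MT1X 481, 458, 562 and 108 CPM, while MT1F and MT3 stayed above DMSO at 17.3 and 5.69 CPM at 14 days against 6.51 and 0.758 CPM. Transcripts of the mitochondrial genome had medians of 0.55 and -0.41 at 4 and 7 days and a relative median of -0.42 at 14 days. Counts of their members moved apart. MT-CYB had 2652 CPM in DMSO and 5676, 2859 and 5972 CPM, whereas MT-ND4L had 1219, 362, 363 and 216 CPM. MT-ND4 had 3306, 4828, 2499 and 3966 CPM. MT-ATP8 had 223 CPM in DMSO and 70.8 CPM at 4 days, and MT-ATP6 4331 and 7952 CPM. How reads were assigned among mitochondrial genes was not examined, so these may not be differences in transcript level. The nuclear genes of oxidative phosphorylation had medians of 0.07 and 0.37 and a relative median of -0.29, with 10 of 34 genes below and 1 above at 14 days, or 5 and 4 by the library total; NDUFA4 had 1842 CPM at 14 days against 1089 CPM in DMSO and ATP5ME 476 against 2286 CPM.

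The dissociation stress list had medians of 0.10 and -0.14 at 4 and 7 days and a relative median of 0.16 at 14 days, with 5 of 13 genes above and 2 below relative to the shift; JUN, at 93.9 CPM against 21.0 CPM in DMSO, and JUNB, at 67.6 against 14.5 CPM, were its highest members. Among Wnt and Notch genes, medians 0.15 and -0.02, the latter 0.03 with equal weight per cell, and a relative median of -0.03 whose sign followed the scale, LEF1 had 13.8 against 0.646 CPM and NOTCH3 15.8 against 2.97 CPM, and the ligand JAG1 14.3 against 51.8 CPM. The Polycomb and DNA methylation list had medians of -0.02 and -0.10 and a relative median of 0.21, with 4 of 19 genes above and 4 below relative to the shift, or 7 and 4 by the library total; among those below, UHRF1 had 0.476 against 12.9 CPM. The hypoxia list had medians of -0.69 and -0.41 and a relative median of -0.03, its sign following the scale, and the endoplasmic reticulum stress list -0.37, -0.17 and a relative -0.40, with PDIA4 at 55.4 against 193 CPM and DDIT3 at 76.0 against 30.2 CPM. The glucocorticoid list had medians of -0.23 and -0.07 and a relative median of -0.43, and the NF-kB list, with 4 members, 0.02, 0.03, which turned to -0.02 with median-of-ratios size factors, and a relative 0.30. The mesenchymal list, with 4 members, had medians of 0.20 and 0.64 and a relative median of 1.22, which reversed with the limit on members; VIM had 5.35 against 1.15 CPM and TWIST1 9.79 against 31.3 CPM. The basal list, with 2 members, had medians of -0.20 and -0.23 and a relative -0.24, and at 14 days its unshifted median of -0.01 turned to 0.04 with equal weight per cell. Of markers of other cell types, 2 fibroblast genes had a relative median of 0.51 at 14 days after 0.24 and 0.39, 0 endothelial and 0 erythroid genes were measured, and the only immune gene was HLA-DRA, which presents peptides on the cell surface, with 0.0292 CPM in DMSO and 1.00, 3.57 and 19.8 CPM.

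All 3 patterns below were found in these data, and the tests of free RNA, of the scale, of doublets and of the mitochondrial share were chosen only after the results had been seen, as were the genes named for these cells. In the 14-day library, 335 of 6024 thinned cells (5.56%, 5.00 to 6.17) had at least 5 KLK3 UMIs and held 83.2% of KLK3 UMIs, against 64.3% of DMSO cells, 1.14% of 4-day cells and 0.799% of 7-day cells, which held 91.1%, 54.1% and 58.9% of the KLK3 UMIs of their libraries. Cells carried over from a DMSO culture are argued against, since 14 other genes at least 20 times lower at 7 days than in DMSO stood in these cells at a median of 5.66% of their DMSO level (1.12 to 17.7), with HPGD at 0.969 CPM. Free RNA is argued against, since the 10% of cells with most KLK3 held 95.9% of it where Poisson counts would give 31.8%, and so is the scale, since the difference from 7 days was 2.80 with median-of-ratios size factors. Against the other 14-day cells these cells had more KLK2 (131 and 4.47 CPM), KLK4 (503 and 96.4 CPM), AZGP1 (85.3 and 17.4 CPM) and TRGC1 (21.5 and 2.04 CPM), less UGT2B17 (102 and 469 CPM) and UGT2B15 (17.5 and 101 CPM), and other androgen-induced genes, FKBP5 (14.8 and 11.4 CPM) among them, were higher by a median of 0.31 (0.15 to 0.45). A candidate explanation is that part of the culture regained transcripts of some androgen-induced genes under the drug, or that the few cells that kept KLK3 at 4 and 7 days became a larger share, and 1 library per time separates neither from a feature of this culture.

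A cluster low in MALAT1, a nuclear noncoding RNA, held 14.3% of 7-day cells (13.7 to 15.0) and 0.515%, 0.384% and 1.71% of DMSO, 4-day and 14-day cells. Its 7-day cells had 8357 CPM of MALAT1 against 33732 CPM in the other 7-day cells, less NEAT1 (502 and 1325 CPM), KCNQ1OT1 (6.40 and 30.9 CPM) and MKI67 (13.9 and 44.9 CPM), and more RPL29 (6668 and 4019 CPM). Damage with loss of cytoplasm is argued against by a mitochondrial share lower by -0.59 percentage points (-0.67 to -0.52). Over 243 long noncoding genes, MALAT1 and NEAT1 left out, the median difference was 0.18 (0.09 to 0.21), above the -0.33 of 5570 coding genes. These genes were taken by annotation and not by place in the cell. They went both ways, with FTX lower (15.3 and 54.0 CPM) as KCNQ1OT1 was. A loss of nuclear RNA therefore stays open. Doublets stay open too, since the median UMI count was 1.27 times that of the other cells (1.19 to 1.33) and no value measured what doublets would give here. The cells may also be a state of this culture or of its handling, and no biological explanation was tested. With cell cycle genes left out of the clustering, a cluster holding 15.5% of 7-day cells was led by OASL, IFIT3, IFIT2 and PLAAT4. How far its cells are those low in MALAT1 was not measured. It held 1725 cells of the 7-day library. Only 14 of 10644 thinned 7-day cells were high in interferon response genes by the rule below, so those can be only a small part of it. Interferon response levels in its other cells were not measured.

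A few cells in every library carried very high interferon response transcripts, with at least 5 UMIs of IFIT1, IFIT2, IFIT3 and OASL together in 5 DMSO cells and 13, 14 and 7 cells at 4, 7 and 14 days. Pooled, these 39 cells had 5075 CPM of ISG15 against 237 CPM in other cells and 195 UMIs of CXCL10, a chemokine, and 11 UMIs of IFNL1, an interferon gene, against 3 in the other cells. Blood cells are argued against by luminal identity genes at a median difference of 0.14 (-0.04 to 0.41) from the other cells and by 0 UMIs of PTPRC and LYZ and only 6 of other immune genes, and evenly spread free RNA by ISG15, which took no part in picking the cells and was higher in them by 4.41 (4.37 to 4.45). They did not set the interferon list median, whose unshifted value was 1.59 at 14 days without them and 1.58 with them. They may be LNCaP cells that sensed nucleic acid or interferon, a hypothesis for which no test was at hand.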
